A study of Arabidopsis thaliana with 12 samples.

How the data were processed

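Small RNA was sequenced in 8 libraries, 2 for each of wild type, nrpb/d/e11-1, iyo-4 and qqt2-2, and bisulfite-treated DNA in 4 libraries, 1 per genotype, all from whole 13-day-old seedlings grown on MS medium. Per the labels, small RNA was purified from gel slices of 18 to 30 nt, RNA was extracted with Trizol, DNA with DNeasy, and bisulfite libraries were made with the Accel-NGS Methyl-Seq kit. The submitters' processing notes name cutadapt 1.12, Bowtie and the genome build TAIR10 without parameters, and the program that aligned and called the bisulfite reads is not given in the sources. The deposited small RNA files hold, for each distinct sequence of 18 to 30 nt, its read count, with no positions. The deposited bisulfite files hold, for each of 42915819 cytosines, its context, its coverage and its methylation level as a fraction; level times coverage was a whole number to within 0.00014. Fractions were turned into methylated reads by this product and levels are given in percent.

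A genome sequence was not used here, and a 3-letter genome was rebuilt from the cytosine positions of both strands, with A and T not told apart. Small RNA sequences were matched to it without mismatches in 3 letters. All 5992578 distinct sequences matched somewhere, 59.7% of distinct 24-nt sequences at 1 place. Of reversed 24-nt sequences 20.2% matched and 7.90% matched at 1 place, a measure of chance matches. At 20, 21 and 22 nt, the lengths counted at miRNA and TAS loci, 51.4%, 39.7% and 28.9% of reversed sequences matched. Counts at these loci can therefore include chance matches. Sequences with more than 100 places, 0.667% of reads, were not placed, and other reads were split evenly over their places. The exact mature sequences of 21 of 21 listed miRNA families fell in an annotated MIR gene. Some also matched elsewhere, such as miR156 with 14 places, 7 of them in a MIR gene. Reads were assigned first to the 45S rDNA, tRNA, snoRNA and snRNA genes and the chloroplast, then, at 20 to 22 nt, to miRNA and TAS loci. The 24-nt mature sequence of miR163 was also assigned to miRNA loci. The rest, other 24-nt reads at miRNA and TAS loci included, were called other nuclear. The mitochondrial genome is not in the files, so its share of the quality list was not measured. Gene names and neighbours came from the RefSeq table. That table gives no transposon families, so classes were protein-coding gene bodies, pseudogenes, sequence within 1 kb of a protein-coding gene and other intergenic sequence, and separately pericentromeres (within 2.5 Mb of the centromere) and chromosome arms. It gives no strand, so both 1-kb flanks of a gene were measured and are called low- and high-coordinate. The listed transposable elements AtMU1, AtGP1, EVD and ONSEN carry the pseudogene label in RefSeq, so the pseudogene class includes transposable elements.

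24-nt reads outside structural RNA were counted in 500-bp windows. Of 205993 windows with a read, 34901 passed edgeR's filterByExpr and were tested with glmQLFit and glmQLFTest, all 8 libraries in 1 fit, genotype as the only term, all matched reads as library size and no TMM factor (biological coefficient of variation 0.0746). The 20- to 22-nt reads of 123 miRNA families and 8 TAS loci, with the 24-nt mature sequence added for miR163, were tested in the same way (0.286). A Benjamini-Hochberg adjusted p under 0.05 was called. Window classes were tested with limma's fry. The 24-nt share, and 8 further measures chosen after the data were seen, were compared between the 2 wild-type and 6 mutant libraries by a two-sided exact permutation test over all 28 splits. Folds against libraries with no read use a floor of 3 counts per library, ratios resting on 1 to 4 reads carry exact counting intervals, and shares of single libraries carry 95% Wilson intervals. A floor of 3 counts was 0.207 to 0.292 RPM.

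Methylation was tested in 100-bp windows with at least 4 cytosines of the context covered by at least 4 reads in both libraries, by Fisher's exact test on pooled reads, with a Benjamini-Hochberg adjusted p under 0.01 and a difference of at least 0.4 in CG, 0.2 in CHG and 0.1 in CHH. Flanks of 1 kb with at least 20 CHH cytosines were tested by the same test. Windows of 500 bp with at least 5 RPM of 24-nt reads on average over the genotypes were compared with windows without reads.

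The tests, comparisons, named genes and most alternatives were set before the data were examined. Named windows are, per mutant, the 8 with the largest decrease and the 8 with the largest increase past the threshold, with every mutant library beyond both wild-type libraries, a mean of at least 10 RPM in the higher genotype and at most 1 window per 10 kb. Named loci are the miRNA and TAS loci past the threshold, at most 10 of lowest p per comparison, and the lists fixed beforehand: 8 TAS loci, 18 conserved miRNA families, miR163, the methylation-controlled loci SDC, FWA, ROS1, MEA, QQS, IBM1, SUP, AtMU1, AtGP1, EVD and ONSEN, the mutated genes, and the quality list of RNA classes. Named flanks are, per mutant, the 8 genes with the largest loss and the 4 with the largest gain of CHH methylation. miR845, named by this rule in qqt2-2, was also given in iyo-4 and nrpb/d/e11-1. That choice, and the choice to describe the mature sequences of miR158, miR165, miR166 and miR319, were made after their values were seen.

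The tests were checked on simulated data. With 200 windows changed in counts that carried no genotype effect, edgeR recovered 79.0%, 82.0% and 83.0% of them for the 3 mutants with 6, 5 and 15 unchanged windows called, and Fisher's exact test recovered 91.5%, 94.5% and 91.5% of 200 CHH windows. Alternatives covered TMM factors, DESeq2 with total reads or its own size factors, reads at miRNA loci or outside structural RNA and chloroplast as library size, no filter on low counts, a replicate block, only reads with 1 place, only the 2 genotypes compared, all lengths at loci, each library left out, other denominators of the 24-nt share, and for methylation other coverage minimums, windows, thresholds, weights and a correction by the chloroplast level. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0, pyarrow 21.0.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.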

Results

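Whole 13-day-old Arabidopsis thaliana Col-0 seedlings of 4 genotypes were measured: the wild type and the mutants nrpb/d/e11-1, iyo-4 and qqt2-2. The wild-type libraries are titled L1 in the labels. MINIYO (IYO) is a homologue of the RNA polymerase II associated protein RPAP1, QUATRE-QUART2 (QQT2) is a GPN-loop GTPase, and NRPB/D/E11 is a subunit shared by RNA polymerases II, IV and V. Small RNAs of 18 to 30 nt were sequenced in 8 libraries, 2 per genotype, with 10270657 to 14464472 reads per library. Whole-genome bisulfite sequencing gave 1 library per genotype, with 671011419 reads over cytosines in wild type, 620886541 in iyo-4, 694620763 in qqt2-2 and 698915124 in nrpb/d/e11-1, a mean coverage of 15.6, 14.4, 16.1 and 16.2 reads per nuclear cytosine. Nothing in the labels says that the 2 small RNA libraries of a genotype came from separate plants, so p-values measure only the spread between these samples. Reads carried no molecular identifiers, so intervals and floors cover counting error only. The mutated genes come first: CHH methylation over the IYO gene body was 0.850% in wild type and 0.578% in iyo-4, over QQT2 0.912% and 0.693% in qqt2-2, and over the gene of subunit 11 0.555% and 0.451% in nrpb/d/e11-1. Neither assay reads the mutations or the mRNA, so these values check no label.

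The small RNA libraries asked whether IYO, QQT2 and NRPB/D/E11 are needed to make 24-nt siRNAs, the small RNAs that guide DNA methylation. 24-nt reads were 26.5% ± 1.28 (SD, n = 2) of all matched reads in wild type, 11.6% ± 0.449 in iyo-4, 15.0% ± 0.344 in qqt2-2 and 11.66% ± 0.977 in nrpb/d/e11-1, each with n = 2. 24-nt reads outside structural RNA, chloroplast and mature miR163 numbered 197318 ± 16410 (SD, n = 2) reads per 1e6 matched reads (RPM) in wild type. Other 24-nt reads at miRNA and trans-acting siRNA (TAS) loci are included. These 24-nt reads were 10.7-fold lower in iyo-4 (18451 ± 1883 RPM), 3.01-fold lower in qqt2-2 (65574 ± 5064 RPM) and 28.9-fold lower in nrpb/d/e11-1 (6823 ± 136 RPM). Distinct 24-nt sequences, thinned to 10270657 reads per library, numbered 801180 in wild type, 105783 in iyo-4, 376760 in qqt2-2 and 43268 in nrpb/d/e11-1 on average. The 23-nt reads of the same class stood at 53279 RPM in wild type, 5923 RPM in iyo-4, 16391 RPM in qqt2-2 and 4555 RPM in nrpb/d/e11-1. The 22-nt reads, counted without miRNA and TAS loci, stood at 29148, 10512, 21132 and 6672 RPM. The share of these 24-nt reads that began with A, the first base favoured by ARGONAUTE4, was 64.4% in wild type, 48.6% in iyo-4, 57.2% in qqt2-2 and 36.4% in nrpb/d/e11-1.

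Fragments of the 45S rDNA made up 53.4% ± 2.93 (SD, n = 2) of reads in wild type, 78.6% ± 3.30 in iyo-4, 68.8% ± 3.42 in qqt2-2 and 87.3% ± 1.19 in nrpb/d/e11-1, so 24-nt reads in the mutants came largely from rDNA: 77.2% in iyo-4, 51.8% in qqt2-2 and 89.8% in nrpb/d/e11-1 against 23.02% in wild type. Per miRNA read, rDNA reads numbered 11.4 in wild type, 19.4 in iyo-4, 12.4 in qqt2-2 and 47.3 in nrpb/d/e11-1 (two-sided exact permutation p 0.357, 0.357 adjusted). The other classes of the quality list were tRNA fragments (2.36%, 3.35%, 3.01% and 3.29% of reads in wild type, iyo-4, qqt2-2 and then nrpb/d/e11-1), snoRNA and snRNA fragments (0.170%, 0.281%, 0.217% and 0.212%) and chloroplast reads (1.15%, 2.76%, 1.76% and 1.05%). Across the 3 mutants together, the 24-nt share was 12.7% against 26.5% in wild type, a difference of -13.8 points (two-sided exact permutation test over 28 splits, p = 0.0357, the smallest these splits allow). Single libraries ranged from 10.97% (95% Wilson interval 10.95 to 10.99) in nrpb/d/e11-1 replicate 1 to 27.42% (27.40 to 27.45) in wild-type replicate 1. Of 8 further measures tested the same way, 24-, 23- and 22-nt RPM and the rDNA share each gave p = 0.0357 in an exact permutation test (0.0714 after Benjamini-Hochberg adjustment), and 21-nt RPM, the share of 25- to 30-nt reads and the 5′ A share gave p = 0.0714 (0.0816 adjusted). A single mutant against wild type could not reach 0.05, since 2 against 2 libraries allow no exact p below 0.333. The difference did not pass the exact test per distinct sequence (-20.3 points, p = 0.0714) or per miRNA read (-1.68 reads, p = 0.393, with 24-nt rDNA fragments counted). It was -12.9 points without wild-type replicate 1 and -14.7 points without replicate 2, where the 7 splits left allow no exact p below 0.143.

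**Figure D1:**
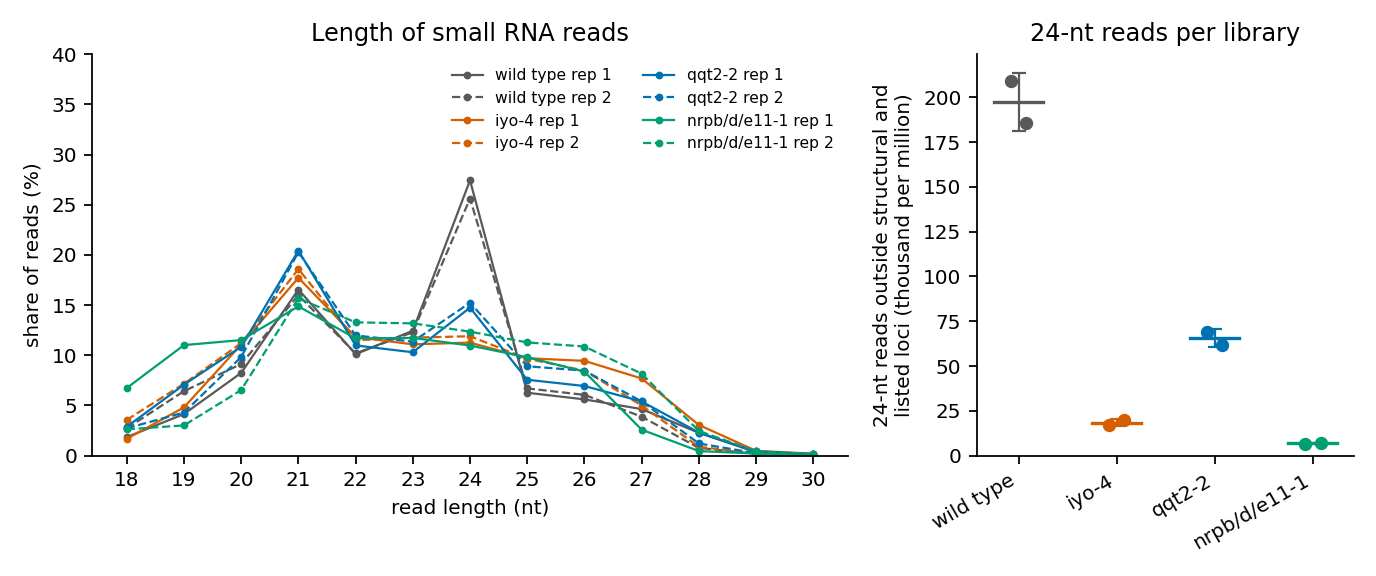
Left, share of reads (%) at each length from 18 to 30 nt, 1 line per library. Right, 24-nt reads outside structural RNA, chloroplast and mature miR163 per library, scaled as on the axis, with 1 point per library, the mean as a bar and its SD (n = 2). The 24-nt share was 26.5% in wild type, 11.6% in iyo-4, 15.0% in qqt2-2 and 11.66% in nrpb/d/e11-1.

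In iyo-4, 24-nt siRNAs were lower in nearly all windows with enough reads to be tested, with all matched reads as library size. The window in the 3BETAHSD/D1 gene body, a sterol synthesis gene (chromosome 1, 17335501 to 17336000, TAIR10), held 73.5 ± 6.11 RPM (SD, n = 2) in wild type and no read in either iyo-4 library, at least 273-fold lower against a floor of 3 counts per library (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p 1.31e-11), and its CHH methylation stood at 37.7% in wild type and 0.248% in iyo-4. Windows at the gibberellin synthesis gene GA3OX2 (chromosome 1, 30200001 to 30200500, 39.6 ± 4.23 RPM in wild type), in AT4G09490 (chromosome 4, 6016001 to 6016500) and near AT5G05140 (chromosome 5, 1518501 to 1519000) were at least 147-, 145- and 144-fold lower, and those in AT1G19410, near BBX12, at the MADS-box gene AGL76 and near AT3G00820 at least 123-fold lower. The 2 largest gains were at miRNA genes: the 24-nt reads of the MIR5020b window (chromosome 4, 6787001 to 6787500) rose from 11.6 ± 4.59 to 215 ± 51.5 RPM (18.5-fold, adjusted p 5.19e-10 by edgeR) and those of the MIR160c window (chromosome 5, 19009001 to 19009500), a source of the miRNA that targets auxin response factors, from 2.31 ± 0.527 to 10.3 ± 0.774 RPM (4.46-fold). The other 6 named gains, at HVA22H, AT1G09805, MIR158a, near AT5G55010, near FRD3 and at RWA3, were 1.45- to 2.97-fold, and the HVA22H value varied between replicates (105 ± 73.7 RPM in iyo-4). The calls at HVA22H and near FRD3 were lost without either wild-type library (adjusted p by edgeR 0.0805 and 0.158 without replicate 1, 0.067 and 0.358 without replicate 2). The FRD3 call was also lost without iyo-4 replicate 2 (0.566) and with DESeq2 and total reads as size (0.0661), and that at RWA3 without wild-type replicate 2 (0.0788). Of 34901 windows of 500 bp tested, 34041 were lower and 123 higher in iyo-4 by edgeR's quasi-likelihood test with adjustment by Benjamini-Hochberg. The median log2 change was -4.46, or -2.84 with windows at 0 set at their floor, and summed 24-nt reads were 12.1-fold lower. In all, 6553 of the lower windows (19.3%) had no read in iyo-4. Without wild-type replicate 1, 73 windows were higher.

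In qqt2-2 the loss was smaller and left windows with partial signal. No qqt2-2 read was left near AT1G06983 (chromosome 1, 13837501 to 13838000), where 23.3 ± 0.909 RPM (SD, n = 2) in wild type fell to 0 (at least 96.3-fold lower, adjusted p 3.64e-10 by edgeR), at AT1G27000 (chromosome 1, 9373501 to 9374000, at least 61.0-fold) and near SDH2-3, which encodes a succinate dehydrogenase subunit (chromosome 5, 26037501 to 26038000, at least 43.5-fold). The window in the glycosyl hydrolase gene GH9B12 (chromosome 2, 18396001 to 18396500) fell from 75.3 ± 0.569 to 0.161 RPM, a ratio of 466 (95% counting interval 182 to 1712) that rests on 4 qqt2-2 reads. Windows at AT4G29710, AT2G15320 and near AT4G05870 kept 1 read each (ratios of 479, 474 and 462, with counting intervals of 85.6 to 18950, 84.7 to 18770 and 82.5 to 18290), and the AT5G22560 window kept 2 (408, 113 to 3372). The largest gain was in the pseudogene AT3G43828 (chromosome 3, 15677501 to 15678000), which rose from 5.09 ± 0.918 to 37.9 ± 2.85 RPM (7.46-fold, adjusted p 8.14e-10) and stood at 7.44 RPM in iyo-4 and 2.22 RPM in nrpb/d/e11-1. MIR5020b rose 6.87-fold to 79.8 ± 3.38 RPM (adjusted p 9.07e-08), and the windows at AT2G31140, Pnsl5, AT4G04565, ABAP1, near AT5G55010 and at AT1G75710 rose 1.87- to 2.24-fold. The calls at Pnsl5 and AT4G04565 were lost without wild-type replicate 1 (adjusted p by edgeR 0.0674 and 0.0502) or replicate 2 (0.0501 and 0.0659), and that at AT4G04565 also with reads at miRNA loci as library size (0.0716). Of the 34901 windows, 28567 were lower and 341 higher (edgeR), the median log2 change was -1.77 (-1.78 with the floor) and summed reads were 3.19-fold lower. In all, 246 of the lower windows (0.861%) held no qqt2-2 read. Without wild-type replicate 1, 178 windows were higher, and without replicate 2, 154.

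In nrpb/d/e11-1 24-nt siRNAs were all but absent. Near AT1G47395 (chromosome 1, 17382001 to 17382500) 134 ± 0.847 RPM (SD, n = 2) in wild type fell to 0, at least 571-fold lower (adjusted p 1.06e-11 by edgeR), and at AT3G00430 (chromosome 3, 8752001 to 8752500) 116 ± 0.934 RPM fell to 0, at least 498-fold lower. The windows near the transcription factor gene MYB3R-5 (chromosome 5, 486501 to 487000), at the carboxylesterase gene CXE18, at AT4G29780 and AT3G07110, near AT2G13463 and near the isocitrate dehydrogenase gene IDH-IV also held no read, at least 404- to 473-fold lower. MIR5020b rose 20.2-fold to 234 ± 12.7 RPM (adjusted p 2.47e-10) and MIR160c 5.01-fold to 11.6 ± 2.10 RPM. The lncRNA locus AT1G05163 rose from 69.9 ± 10.3 to 131 ± 0.723 RPM (1.87-fold), and the windows near AT2G14970, at AT4G04565, AT1G66290 and AT2G31141 and near FRD3 rose 1.51- to 1.95-fold. With only reads of 1 place the AT1G66290 window was lower instead (log2 change -6.68). The calls near AT2G14970 and FRD3 were lost without wild-type replicate 1 (adjusted p by edgeR 0.0555 and 0.164) or replicate 2 (0.289 and 0.375). The FRD3 call was also lost without nrpb/d/e11-1 replicate 1 (0.377), with a replicate block (0.0545) and with DESeq2 and total reads as size (0.0777). That at AT1G66290 was lost without wild-type replicate 2 (0.0565), and that at AT2G31141 without wild-type replicate 1 (0.0862) or nrpb/d/e11-1 replicate 2 (0.0564). Of the windows, 34369 were lower and 123 higher (edgeR). The median log2 change was -7.47, or -3.11 with the 29851 lower windows (86.9%) that had no nrpb/d/e11-1 read at their floor, and summed reads were 39.9-fold lower. Without wild-type replicate 1, 78 windows were higher.

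The split between lower and higher windows rested on the library size. With all matched reads, 0.360% of called windows were higher in iyo-4, 1.18% in qqt2-2 and 0.357% in nrpb/d/e11-1. With TMM factors computed on the windows themselves, 32.6%, 45.4% and 9.53% were higher (4603 lower and 2222 higher, 8891 and 7403, and 9883 and 1041). The median log2 changes then moved to -0.50 in iyo-4 and 0.03 in qqt2-2. The median of -5.95 in nrpb/d/e11-1 comes mostly from windows with no read there, follows the depth in wild type and bounds no fold. With reads at miRNA loci as library size, 30251 windows were lower and 179 higher in iyo-4, 28162 and 93 in qqt2-2 and 30334 and 615 in nrpb/d/e11-1, with medians of -4.32, -2.13 and -7.39. With reads outside structural RNA and chloroplast as library size, 5.38%, 11.4% and 4.69% of called windows were higher. The gains at MIR5020b in all 3 mutants, and at MIR160c in iyo-4 and nrpb/d/e11-1, passed under each of these sizes. In iyo-4 and nrpb/d/e11-1 each alternative size raised the log2 change of both windows, so passing there does not test the gains. In qqt2-2 reads at miRNA loci lowered that of MIR5020b from 2.77 to 2.52, and the other sizes raised it.

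Setting the mutants against each other showed how far each loss went. qqt2-2 kept more 24-nt siRNAs than iyo-4 in 27472 windows and fewer in 67, with a median log2 difference of 2.65, and nrpb/d/e11-1 held fewer than qqt2-2 in 32447 windows and more in 92 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment, n = 2 libraries each). nrpb/d/e11-1 lay below iyo-4 in 5276 windows and above it in 22. The window near AT1G47395 kept 7.91 RPM in qqt2-2, 0.328 in iyo-4 and 0 in nrpb/d/e11-1, and that in 3BETAHSD/D1 3.07, 0 and 0.0806 RPM. The 5298 windows that differed between nrpb/d/e11-1 and iyo-4 became 2858 without iyo-4 replicate 1, and without its replicate 2 they became 2180 below and 12 above iyo-4. They became 1098 without nrpb/d/e11-1 replicate 1 and 955 without its replicate 2. They became 1749 with TMM factors, 818 with reads at miRNA loci as library size and 1098 with DESeq2 and its own size factors. The 27539 windows that differed between qqt2-2 and iyo-4 became 1805 with TMM factors, 8021 with DESeq2 and its own size factors and 12457 with reads outside structural RNA and chloroplast as library size. The 32539 between nrpb/d/e11-1 and qqt2-2 became 8458, 15062 and 17115.

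Most tested windows were lower in each mutant, so the lists of lower windows overlapped almost fully with or without a shared effect. Windows lower in both iyo-4 and qqt2-2 numbered 28543, where independent lists would share 27863. In iyo-4 and nrpb/d/e11-1 they numbered 34017 (33522) and in qqt2-2 and nrpb/d/e11-1 28544 (28132). In all, 28535 were lower in all 3 mutants. Windows higher in both numbered 58, 53 and 41 for these pairs, where independent lists would share 1.20, 0.433 and 1.20, and the 27 higher in all 3 included MIR5020b. In 10 simulations with no genotype effect and the same shared wild-type libraries, the lists shared 0 windows. That count shows what the shared controls alone call and does not measure the overlap of lists that hold effects. The covariance of the log2 changes was 1.92, 2.03 and 1.18, beside 0.0438, 0.0441 and 0.0441 in the simulations, and their correlation 0.686, 0.552 and 0.458, beside 0.468, 0.475 and 0.488. Wild-type libraries could not be split with at least 2 each, so part of the excess may come from the shared controls.

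By position, 24-nt reads in qqt2-2 fell least in pseudogenes and most within 1 kb of genes, both as the median log2 change (-1.17 and -2.81) and as summed reads. In iyo-4 the median gave the same order (-3.91 and -5.74, or -2.53 and -3.54 with the floor), but the summed loss was largest in pseudogenes. The summed loss of nrpb/d/e11-1 was largest there too, and its medians (-7.21 and -8.14) rank no class, because most windows held no read and the value then follows the depth in wild type. Within 1 kb of protein-coding genes, summed 24-nt reads were 61282 ± 3884 RPM (SD, n = 2) in wild type and 14.4-fold lower in iyo-4, 4.72-fold in qqt2-2 and 46.8-fold in nrpb/d/e11-1. In pseudogenes, 21725 ± 1964 RPM in wild type became 1420 ± 110 in iyo-4 (15.3-fold lower), 10135 ± 319.2 in qqt2-2 (2.14-fold) and 95.1 ± 4.07 in nrpb/d/e11-1 (228-fold). Gene bodies were 7.51-, 2.77- and 17.4-fold lower, other intergenic sequence 11.8-, 2.92- and 40.5-fold, chromosome arms 10.9-, 4.04- and 30.8-fold and pericentromeres 14.7-, 2.39- and 75.1-fold in iyo-4, in qqt2-2 and in nrpb/d/e11-1. In iyo-4, 8900 of 8930 tested pseudogene windows were lower and 2 higher, against 3997 and 82 of 4552 gene-body windows. The counts were 6355 and 54 against 3620 and 146 in qqt2-2, and 8922 and 0 against 4159 and 75 in nrpb/d/e11-1 (edgeR). limma's fry, which tests whether a set moves one way on balance, put every class down in every mutant (adjusted p from 4.31e-05 to 0.000401). With TMM factors on the windows the direction by fry turned up for gene bodies (adjusted p 0.000208), pseudogenes (0.0696) and pericentromeres (0.0170) in iyo-4, and for other intergenic sequence (0.00872), pseudogenes (4.31e-05) and pericentromeres (1.77e-05) in qqt2-2.

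**Figure D2:**
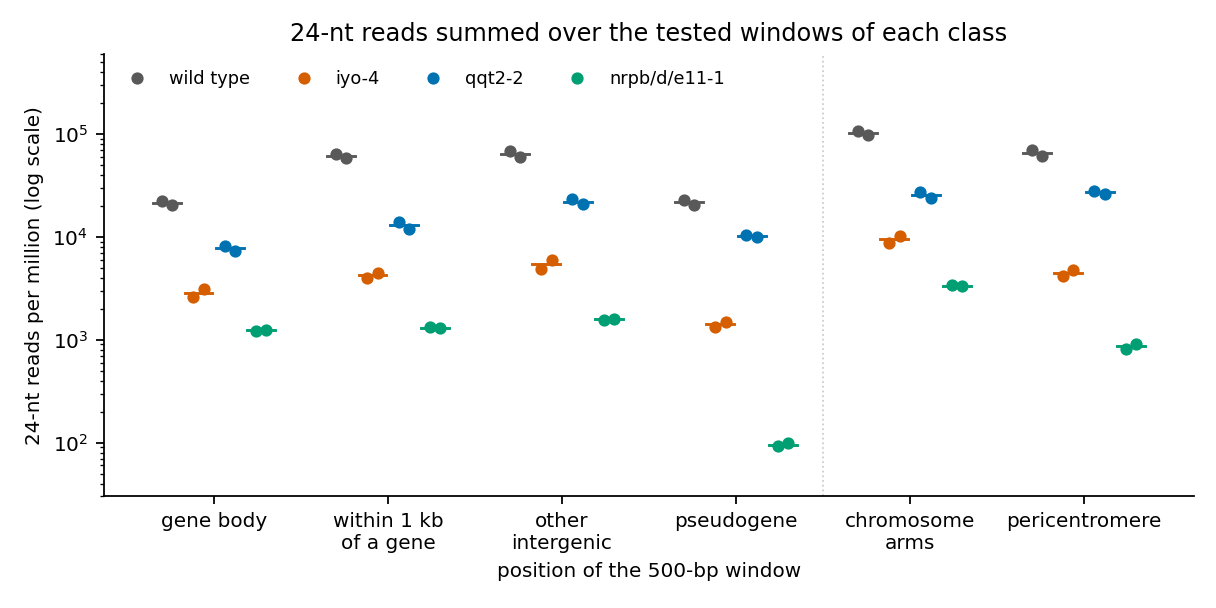
24-nt RPM summed over the tested 500-bp windows of each class (log axis), 1 point per library and a line at the mean of 2. Pseudogene windows summed to 21725 RPM in wild type, 1420 in iyo-4, 10135 in qqt2-2 and 95.1 in nrpb/d/e11-1.

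Among 131 miRNA families and TAS loci with 20- to 22-nt reads (for miR163 also its 24-nt mature sequence), many of the losses in iyo-4 and qqt2-2 were at families with few reads. In iyo-4, miR5635 fell from 12.7 ± 0.0584 to 1.26 ± 0.152 RPM (SD, n = 2; log2 change -3.33 ± 0.23 SE, adjusted p 0.000108 by edgeR), miR5645 and miR854 fell by 3.24 and 3.07 on the log2 scale, and miR8167 (3.31 to 0.0410 RPM), miR8180 (1.97 to 0.0821 RPM) and miR5665 (log2 change -2.02) fell as well. miR8172, miR5644 and miR8169, at 1.33, 2.85 and 1.83 RPM in wild type, had no read in iyo-4. miR5020 rose from 2.64 ± 0.768 to 53.2 ± 16.4 RPM (log2 change 4.32 ± 0.36), and miR845, a family that matches retrotransposons, from 27.1 ± 4.47 to 62.1 ± 22.4 RPM (log2 change 1.19, adjusted p 0.0301). The miR845 call was lost without wild-type replicate 1 (adjusted p 0.1154 by edgeR), wild-type replicate 2 (0.2166) or iyo-4 replicate 1 (0.147). Those at miR5644, miR8180 and miR8169 were lost without wild-type replicate 1 (0.0782 to 0.0894), and those at miR5644, miR8172, miR8180, miR8169 and miR5665 without wild-type replicate 2 (0.0547 to 0.0851). The miR5665 call was also lost without iyo-4 replicate 1 (0.0676) or replicate 2 (0.0526), and with DESeq2 and its own size factors miR5644 (0.405) and miR5665 (0.0865) were lost. In all, 15 loci were lower and 5 higher by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a median log2 change of -0.06. Of the 8 TAS loci and 18 conserved miRNA families fixed beforehand, none passed in iyo-4 (0 also adjusted over the list alone). TAS1c stood at 4971 RPM against 4244 in wild type. With reads outside structural RNA and chloroplast as library size, 5 loci were lower and 108 higher of 124, with a median log2 change of 1.503. In wild type 24-nt reads made up 46.8% of that size, against 12.9% in iyo-4, so their loss alone raises every locus on this scale. The lower and higher counts were 7 and 1 without wild-type replicate 1, 4 and 1 without wild-type replicate 2, 8 and 1 without iyo-4 replicate 1 and 13 and 4 without iyo-4 replicate 2.

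In qqt2-2, miR5635 and miR5645 also fell (log2 changes of -1.93 and -1.89), as did miR8167 (-3.50), and miR5644 had no read. miR845 rose to 124 ± 1.79 RPM (log2 change 2.19 ± 0.29 SE, n = 2, adjusted p 0.00241 by edgeR), miR5020 to 21.5 ± 0.681 RPM (3.02), miR5634 to 3.801 RPM (1.74), miR778 to 2.67 RPM (1.38) and miR4228 to 2.99 RPM (1.13). TAS4, whose siRNAs target MYB genes of anthocyanin synthesis, rose from 75.4 ± 6.24 to 168.4 ± 0.126 RPM (log2 change 1.16 ± 0.23, adjusted p 0.0153). With TMM factors on these loci it did not pass (0.61, adjusted p 0.238), nor did miR778 (0.84, adjusted p 0.108) or miR4228 (0.58, adjusted p 0.206). Without wild-type replicate 1 the calls at TAS4, miR4228 and miR5644 were lost (adjusted p 0.0672 to 0.0739 by edgeR), and without wild-type replicate 2 those at TAS4, miR845, miR778, miR4228, miR5644 and, narrowly, miR5634 (up to 0.123). TAS4 and miR4228 were also lost without qqt2-2 replicate 1 (0.0543 and 0.0625) or replicate 2 (0.0526 and 0.0751), and miR778 without qqt2-2 replicate 2 (0.0575). With DESeq2 and its own size factors TAS4, miR5634, miR778, miR4228 and miR5644 were lost (0.104 to 0.617), and with reads of all lengths miR4228 (0.0619). In all, 11 loci were lower and 15 higher, with a median log2 change of 0.40. TAS4 was the single call among the 8 TAS loci and the 18 conserved families had none (1 and 0 also adjusted over the list alone). TMM factors gave 17 lower and 4 higher, with a median of -0.17, and reads outside structural RNA and chloroplast as library size gave 4 lower and 96 higher of 124, with a median of 1.15. The counts were 4 and 4 without wild-type replicate 1, 3 and 1 without wild-type replicate 2, 8 and 4 without qqt2-2 replicate 1 and 9 and 4 without qqt2-2 replicate 2.

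In nrpb/d/e11-1 the loss reached abundant families when all matched reads set the scale. The phosphate-responsive miR399 fell from 260 ± 14.6 to 35.1 ± 1.97 RPM (SD, n = 2; log2 change -2.89 ± 0.23 SE, adjusted p 7.68e-05 by edgeR), miR5635 to 0.274 RPM (-5.49), miR5645 by 4.70 on the log2 scale, miR827 by 4.08, miR5996 by 3.35 and miR3932 by 2.76. miR398, which targets copper superoxide dismutases, stood at 1092 ± 102 RPM against 5547 ± 14.2 in wild type (log2 change -2.35, adjusted p 0.000227; 0.04 with reads outside structural RNA and chloroplast as library size). TAS1c, a source of trans-acting siRNAs, stood at 1411 ± 130 RPM against 4244 ± 345 (-1.59, adjusted p 0.000592; 0.80 with that library size). miR8167 and miR854 held 0.0377 and 0.0403 RPM, and miR845 fell to 6.36 ± 0.247 RPM (-2.09, adjusted p 0.001301; 0.31 with that library size). miR5020 rose to 88.5 ± 18.6 RPM (5.05; 5.99 with TMM factors and 7.48 with that library size). In all, 61 loci were lower and 4 higher, with a median log2 change of -0.86. TMM factors moved the median to 0.06 and gave 34 lower and 28 higher, and reads outside structural RNA and chloroplast as library size moved it to 1.66 and gave 8 lower and 94 higher of 124. The counts were 38 and 3 without wild-type replicate 1, 57 and 2 without wild-type replicate 2, 68 and 4 without nrpb/d/e11-1 replicate 1 and 54 and 5 without nrpb/d/e11-1 replicate 2.

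Of the 8 TAS loci 7 were lower and 0 higher in nrpb/d/e11-1 with all matched reads, 2 and 0 with TMM factors, and 0 and 8 with reads outside structural RNA and chloroplast as library size. Of the 18 conserved miRNA families 8 were lower and 0 higher, 4 and 4 with TMM factors, and 0 and 14 with that size. The lists gave 7 and 8 lower adjusted over the list alone as well. Among conserved families miR396 (log2 change -2.14), miR156 (-1.80) and miR162 (-1.49) passed beside miR398. miR165 (-1.83, adjusted p 0.183 by edgeR), whose replicates stood far apart, did not pass. miR173 (-0.12) and miR390 (-0.08) stayed near 0 with all matched reads but rose by 0.78 and 0.84 with TMM factors. With reads outside structural RNA and chloroplast as library size, 8 of 8 TAS loci and 15 of 18 conserved families were also higher in iyo-4 and in qqt2-2. The long miRNA miR163, counted with its 24-nt mature sequence, stood at 327 ± 44.1 RPM in nrpb/d/e11-1 against 890.6 ± 98.4 (SD, n = 2) in wild type. Its log2 change was -1.45 (adjusted p 0.0269 by edgeR), -0.56 with TMM factors (adjusted p 0.231 by edgeR) and 0.94 with reads outside structural RNA and chloroplast. It did not pass in iyo-4 or qqt2-2. Without wild-type replicate 1 the nrpb/d/e11-1 calls at TAS1a, TAS3a, TAS3b, TAS4, miR159, miR168 and miR163 were lost (adjusted p 0.0524 to 0.199 by edgeR), and without wild-type replicate 2 those at TAS1a, TAS4 and miR163 (0.0608 to 0.0756). That at TAS4 was lost without nrpb/d/e11-1 replicate 1 (0.197), and those at TAS3a, TAS3b, miR168 and miR163 without its replicate 2 (0.0633 to 0.129). The exact mature sequence of miR158 had 707 reads in nrpb/d/e11-1 replicate 2 and 52462 in replicate 1, and those of miR165, miR166 and miR319 stood at 485, 3908 and 253 reads against 10531, 28870 and 2579. These sequences were also lower in qqt2-2 replicate 2 than in its replicate 1. Between mutants, miR845 was lower in nrpb/d/e11-1 than in qqt2-2 (log2 difference -4.28, adjusted p 0.000104) and than in iyo-4 (-3.29, adjusted p 0.000909), and with TMM factors too (-2.84 and -2.45). The TAS4 difference from qqt2-2 (-1.90, adjusted p 0.000479) was -0.43 (adjusted p 0.290) with TMM factors.

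**Figure D3:**
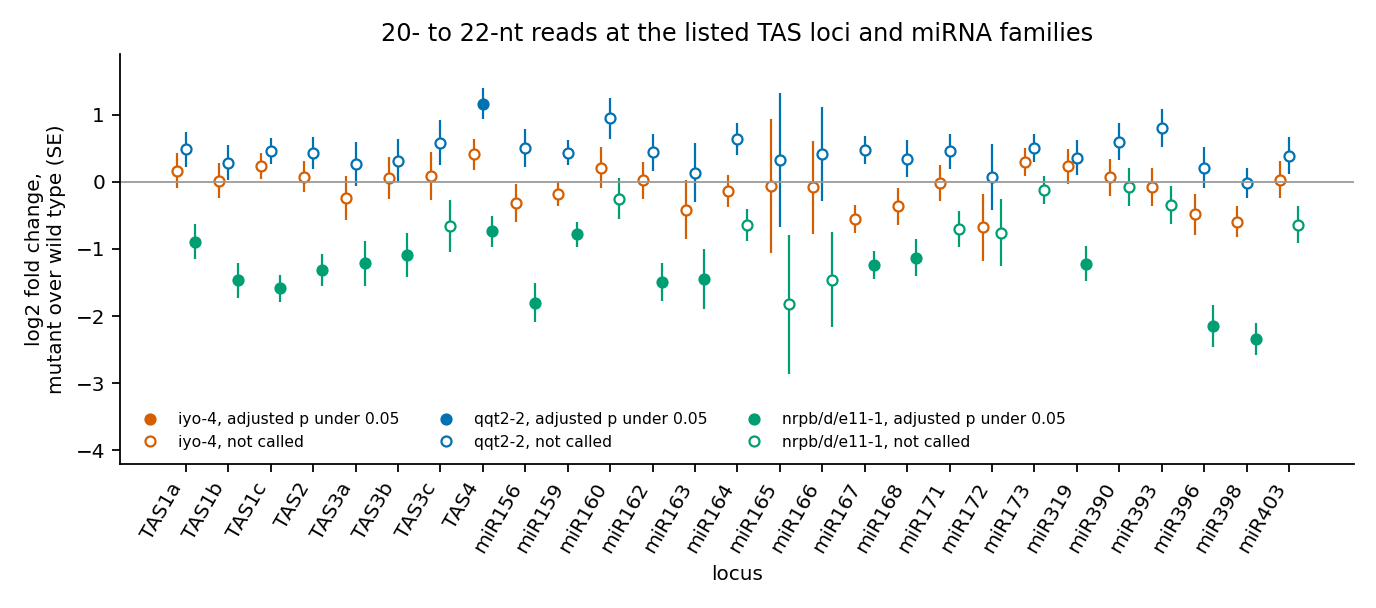
Log2 change of 20- to 22-nt reads at the listed TAS loci and miRNA families, mutant over wild type with all matched reads as library size (bars, SE; filled points, adjusted p under 0.05 by edgeR, 2 libraries per genotype). The nrpb/d/e11-1 values include TAS1c (-1.59) and miR398 (-2.35), which turn to 0.80 and 0.04 with reads outside structural RNA and chloroplast as library size.

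The bisulfite libraries asked how the mutations affect the methylome, and the loss was widest at CHH sites, some of which are kept methylated by RNA-directed DNA methylation, and reached CHG sites as well. CHH methylation was 3.64% of reads at nuclear CHH cytosines in wild type, 2.85% in iyo-4 (-0.792 points, 95% counting interval -0.794 to -0.790), 3.30% in qqt2-2 (-0.338, -0.341 to -0.336) and 2.22% in nrpb/d/e11-1 (-1.42, -1.42 to -1.42). CG methylation was 30.9% in wild type and 34.4%, 33.6% and 31.9% in iyo-4, in qqt2-2 and in nrpb/d/e11-1, and CHG methylation 12.9% against 13.62%, 13.9% and 12.2%. The chloroplast level, a measure of incomplete conversion, was 1.04%, 0.930%, 0.939% and 0.959% in the same order. With 1 library per genotype, these values and all methylation tests compare libraries, not genotypes. As a mean over cytosines the CG differences shrank to 0.376, 0.106 and 0.294 points and the CHG differences of iyo-4 and qqt2-2 turned to -0.561 and -0.275 points.

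Within 1 kb of protein-coding genes CHH methylation was 3.28% in wild type, 1.26% in iyo-4, 1.958% in qqt2-2 and 0.999% in nrpb/d/e11-1. Other intergenic sequence stood at 6.32%, 4.13%, 5.12% and 3.24%, gene bodies at 1.123%, 0.969%, 1.03% and 0.843%, chromosome arms at 2.19%, 1.33%, 1.71% and 1.06% and pericentromeres at 8.03%, 7.05%, 7.79% and 5.73%. Pseudogenes went the other way in iyo-4 (11.9%) and qqt2-2 (12.4%) against 11.05% in wild type, and stood at 9.58% in nrpb/d/e11-1. Over pseudogene cytosines with at least 4 reads in all libraries the differences of iyo-4 and qqt2-2 were 0.824 and 1.27 points, and with wild-type coverage as weights 0.292 and 0.762 points. CHG methylation within 1 kb of genes was 9.63% in wild type, 6.13% in iyo-4, 7.56% in qqt2-2 and 5.14% in nrpb/d/e11-1, while in pseudogenes it was 49.4%, 53.1%, 52.8% and 52.6%.

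**Figure D4:**
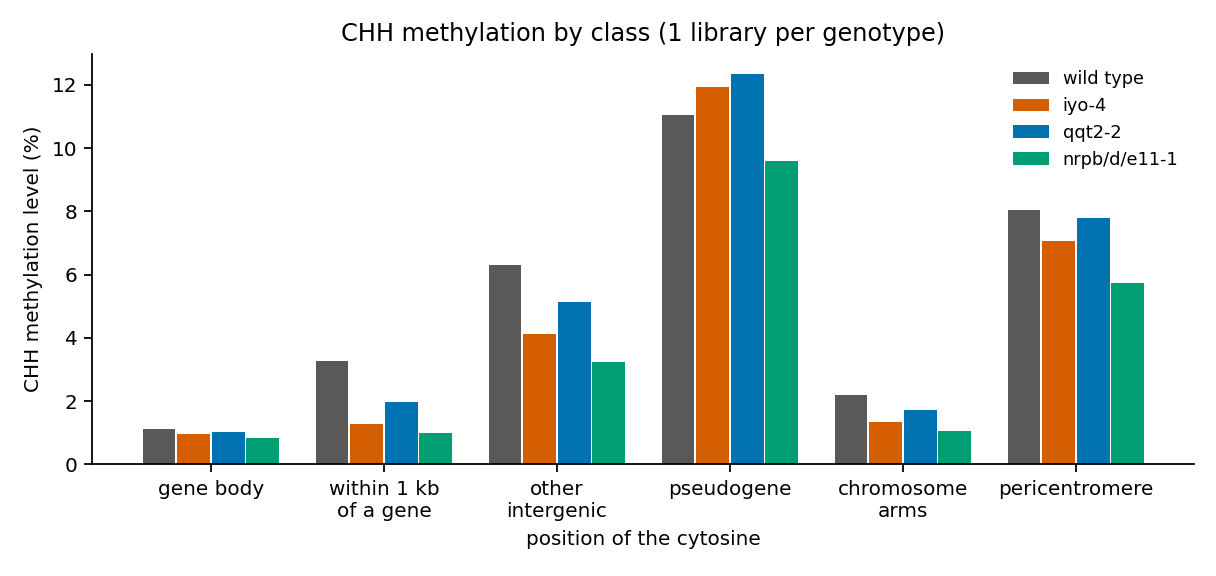
CHH methylation level (%) over 6 classes of nuclear sequence, 1 bar per genotype and 1 library behind each bar. Within 1 kb of protein-coding genes the level was 3.28% in wild type and 0.999% to 1.958% in the mutants; in pseudogenes it was 11.05% in wild type, 11.9% in iyo-4, 12.4% in qqt2-2 and 9.58% in nrpb/d/e11-1.

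Over 100-bp windows, 27208 lost CHH methylation in iyo-4, 17248 in qqt2-2 and 31320 in nrpb/d/e11-1, while 791, 848 and 91 gained it (Fisher's exact test between the 2 libraries, Benjamini-Hochberg adjusted p under 0.01 and a difference of at least 0.1). Over these lost windows, a different list in each mutant and chosen by the loss, the level went from 24.8% to 3.28% in iyo-4, from 28.4% to 10.7% in qqt2-2 and from 24.0% to 2.30% in nrpb/d/e11-1. Windows within 1 kb of genes made up 43.6%, 49.0% and 40.9% of the CHH losses of iyo-4, of qqt2-2 and of nrpb/d/e11-1, against 20.05%, 20.03% and 20.02% of the windows tested. Other intergenic windows made up 45.8%, 40.6% and 46.4% of the losses in the same order, against 16.81%, 16.8% and 16.79% of the windows tested. CHH losses were thus over-represented in both classes. Pseudogenes held 570 of the 791 CHH gains of iyo-4, 587 of 848 in qqt2-2 and 31 of 91 in nrpb/d/e11-1, but 8.35% of the windows tested. CHG losses numbered 10389, 4826 and 12082 against gains of 711, 299 and 940, and CG losses 494, 247 and 1372 against gains of 589, 131 and 767. Of the CHH windows tested in all libraries, iyo-4 and qqt2-2 shared 16814 losses (98.6% of the smaller list, 400 for independent lists), iyo-4 and nrpb/d/e11-1 26385 (97.5%, 730) and qqt2-2 and nrpb/d/e11-1 16928 (99.2%, 460). In all, 16756 were lost in all 3. In 10 simulations with no difference between genotypes and the same wild-type library the lists shared 0, which shows what the shared library alone calls and does not measure the overlap of lists that hold effects. The wild-type library could not be split with at least 2 each, so part of the excess may come from it.

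**Figure D5:**
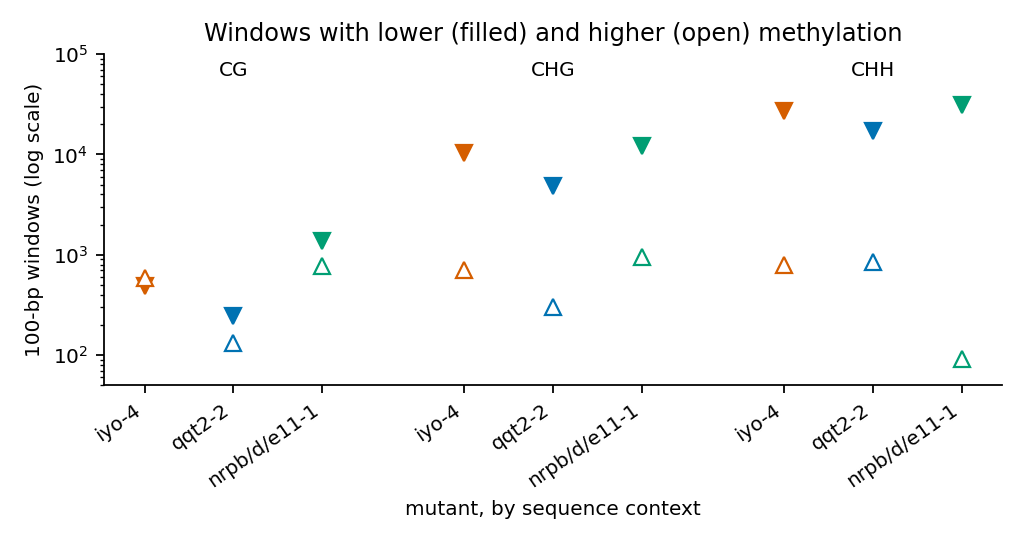
Number of 100-bp windows (log axis) with lower (filled) and higher (open) methylation than wild type, by sequence context and mutant, 1 library per genotype. CHH losses numbered 27208 in iyo-4, 17248 in qqt2-2 and 31320 in nrpb/d/e11-1 against gains of 791, 848 and 91.

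Beside genes, the largest CHH loss in iyo-4 was in a 1-kb flank of DRP3B, which encodes a dynamin-related protein of organelle division, from 50.9% to 10.11%. Flanks of AT2G40420 (42.9% to 2.36%), ORC1A, a subunit of the origin recognition complex (38.2% to 1.27%), its neighbour AT4G14695 (37.6% to 1.33%), PERK4 (36.0% to 1.33%), AT2G20670 (38.3% to 4.94%), AT1G58150 (36.4% to 3.524%) and RLP2 (35.01% to 3.65%) followed. In qqt2-2 the flank of AT2G40420 went from 42.8% to 21.6%, that of AT5G57830 from 35.1% to 13.9%, MVP1 from 27.5% to 7.95%, AT3G13225 from 23.5% to 4.03%, AT4G14695 from 37.1% to 17.9%, PRA8 from 24.1% to 5.04%, MTO1, the gene of cystathionine gamma-synthase, from 23.5% to 4.53% and AT3G44620 from 25.2% to 6.25%. In nrpb/d/e11-1 the flank of AT2G40420 went from 43.4% to 0.651%, DRP3B from 48.9% to 6.77%, AT2G20670 from 37.9% to 0.667% and AT4G14695 from 37.1% to 0.825%. Flanks of AT1G56090 (43.2% to 0.756%), AT1G56100 (41.8% to 0.765%), the meiotic recombinase gene DMC1 (39.8% to 1.16%) and AT3G07140 (37.0% to 0.787%) were lost in nrpb/d/e11-1 but kept more in the other mutants. They stood at 28.4%, 26.2%, 10.7% and 14.1% in iyo-4 and 46.0%, 43.6%, 30.3% and 30.1% in qqt2-2.

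Gains beside genes were smaller. The flank of the resistance gene RPP4 went from 12.8% to 19.4% in iyo-4 (Fisher's exact test, adjusted p 1.73e-17) and from 12.9% to 21.9% in qqt2-2 (adjusted p 5.14e-30), and that of AT5G28340 from 4.88% to 11.67% in iyo-4 (adjusted p 4.15e-11). The overlapping flanks of AT4G20670 and AT4G20650 rose in iyo-4 to 9.52% and 9.29% from 3.01% and 2.93%, and that of AT4G20670 to 6.83% in nrpb/d/e11-1. AT1G65352 (9.37% to 16.5%), AT4G09260 (6.62% to 12.5%) and TOC75-I (12.1% to 18.0%) were the other named gains of qqt2-2, and AT4G09310 (5.78% to 10.4%), AT3G29750 (13.7% to 17.5%) and AT3G44703 (4.503% to 8.28%) those of nrpb/d/e11-1. In all, 8396 flanks were lower and 262 higher in iyo-4, 7776 and 306 in qqt2-2, and 9214 and 67 in nrpb/d/e11-1 (Fisher's exact test, adjusted p under 0.01).

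At loci known to be held by DNA methylation, the F-box gene SDC carried 50.3 ± 3.4 RPM (SD, n = 2) of 24-nt reads and 9.13% CHH methylation in its low-coordinate 1-kb flank in wild type, 3.45 RPM and 3.41% in iyo-4, 12.4 RPM and 6.42% in qqt2-2 and 0.0403 RPM and 2.63% in nrpb/d/e11-1. Over the imprinted homeodomain gene FWA CHH methylation was 2.92%, 0.821%, 1.57% and 0.712% in wild type, iyo-4, qqt2-2 and then nrpb/d/e11-1, with 24-nt reads at 21.4, 0.277, 2.06 and 0 RPM, while CG methylation was 44.5%, 55.8%, 52.4% and 46.8%. The high-coordinate flank of the imprinted Polycomb gene MEA went from 7.83% CHH to 0.964%, 2.16% and 1.05%, and from 19.6% CHG to 0.566%, 6.56% and 1.299%. In the high-coordinate flank of the DNA demethylase gene ROS1, CG methylation was higher in the mutants, 47.9%, 35.2% and 46.8% against 17.6%, and CHH methylation was 1.01%, 2.82% and 0.636% against 3.08%. QQS showed CG methylation of 52.4% in wild type and 67.7%, 63.4% and 70.9% in the mutants in its high-coordinate flank, and the H3K9 demethylase gene IBM1 showed CHG methylation of 4.55% against 8.39%, 6.35% and 5.89% in its body. SUP was near background, with CHH methylation of 0.622% in its body in wild type and 0.357% to 0.571% in the mutants.

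Among transposable elements, the Mutator element AtMU1 stood at 10.09% CHH methylation in wild type, 6.76% in iyo-4, 8.71% in qqt2-2 and 5.94% in nrpb/d/e11-1, and the flank of the Copia element ONSEN at 5.25%, 0.644%, 2.89% and 0.556%. The Gypsy element AtGP1 (13.4% against 14.1%, 16.0% and 11.4%) and the Copia element EVD (13.1% against 15.8%, 16.3% and 10.8%) stood above the wild-type level in iyo-4 and qqt2-2. These levels were not tested. AtMU1, ONSEN, AtGP1 and EVD are all annotated as pseudogenes, the class described above. AtGP1 kept 1.51 RPM of its 30.3 RPM of 24-nt reads in iyo-4, 18.5 RPM in qqt2-2 and 0.0377 RPM in nrpb/d/e11-1.

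Both assays met in the windows that make 24-nt siRNAs. Over the 1847 windows of 500 bp with at least 5 RPM on average across genotypes, CHH methylation was 17.4% in wild type, 4.36% in iyo-4 (-13.0 points), 9.58% in qqt2-2 (-7.81) and 2.57% in nrpb/d/e11-1 (-14.8). Over the 204146 windows with fewer 24-nt reads it was 3.86% in wild type and differed by -0.785, -0.337 and -1.45 points. Over the 32303 windows with no 24-nt read in any library it was 0.706% in wild type, under the chloroplast level of 1.04%. These windows therefore had hardly any methylation to lose, whatever the cause, and differed by -0.0728, -0.0736 and -0.0849 points. Windows with lower 24-nt reads were more often CHH hypomethylated than windows without, with odds ratios of 15.5 in iyo-4 (95% interval 8.54 to 28.1), 72.3 in qqt2-2 (37.6 to 139) and 30.6 in nrpb/d/e11-1 (11.4 to 81.9). They became 9.64, 12.1 and 9.66 with TMM factors and 9.67, 17.3 and 10.06 with a CHH threshold of 0.05, so the differences between mutants rested on these choices. Within quartiles of the wild-type CHH level they became 1.93, 51.1 and 3.95, and no p is given because neighbouring windows are not independent.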

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

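The tests of scaling for the higher windows and of bisulfite conversion were chosen after their results were seen, as was the use of the lower quartile for breakdown; the other tests here were set beforehand.

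Several differences between mutants were large. Windows whose 24-nt reads differed numbered 27539 between qqt2-2 and iyo-4, 5298 between nrpb/d/e11-1 and iyo-4 and 32539 between nrpb/d/e11-1 and qqt2-2 (edgeR's quasi-likelihood test of the difference itself). The miR845 family differed by -4.28 on the log2 scale between nrpb/d/e11-1 and qqt2-2. CHH methylation of pseudogenes differed from wild type by 0.873 points in iyo-4, 1.31 in qqt2-2 and -1.47 in nrpb/d/e11-1, opposite ways in different mutants, and this difference was not tested. Reads of 25 to 30 nt, outside the comparisons set beforehand, were 26.1% of reads in the 6 mutant libraries on average against 18.4% in wild type. The chloroplast share of iyo-4 replicate 2, 4.05%, lay far from those of the other 5 mutant libraries; chance marks about 1 in 20 groups this way, and 4 measures were examined.

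The windows with higher 24-nt reads were weighed first. If breakdown products of longer RNAs were counted at 24 nt, 24-nt reads should be a small share of all lengths there. Their median share in the mutant was 13.96% in iyo-4, 47.81% in qqt2-2 and 15.86% in nrpb/d/e11-1. In wild type it was 11.2%, 44.5% and 12.1% at the same windows and 67.7%, 68.4% and 67.6% at the windows that fell. Breakdown may account for the iyo-4 windows, whose share lay under the 15% set for it, but the share was as low there in wild type and does not show what raised them. In nrpb/d/e11-1 breakdown cannot be told apart, because the share lay between 15% and the 33.8% set against it. In qqt2-2 it cannot be told apart either, because the median passed its limit of 34.2% but the lower quartile, 15.7%, did not. With reads at miRNA loci as library size, 24.63% of the qqt2-2 windows stayed higher, so most of these calls rest on the library size. Whether scaling by all matched reads made them cannot be told apart: miRNA reads were 5.75% of reads in qqt2-2 against 4.69% in wild type, so this size could only lower its windows. In iyo-4 and nrpb/d/e11-1 95.12% and 100% stayed higher, but scaling cannot be told apart there: miRNA reads were 4.09% and 1.94% of reads against 4.69% in wild type, so this size could only raise their windows. An effect of the mutations stays open in all 3.

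The mature sequences of miR158, miR165, miR166 and miR319 were low in nrpb/d/e11-1 replicate 2, with log2 ratios to replicate 1 of -6.31, -4.54, -2.98 and -3.44. If the last bases of the RNA set the loss, sequences of other loci with the same last 2 bases should be low too. Their median ratio was -0.4315 (lower quartile -1.55), beside -0.0987 with other last bases. If length set it, other loci of 20 and 21 nt should be low, and their median was -0.2755 (lower quartile -0.890). Both medians passed the limit set against these causes. At 20 nt alone, the length of miR158, the median was -0.834 (lower quartile -1.44), beside -0.0325 at 22 nt. However, all 43 sequences of the low families had a median of only -0.650 (lower quartile -2.01). The mature sequences were chosen after their values were seen, so these medians decide on neither cause. The same sequences were also lower in qqt2-2 replicate 2 than in its replicate 1. There miR158 stood at 3302 against 11426 RPM, miR165 at 1235 against 2714, miR166 at 3691 against 6173 and miR319 at 321 against 610. For comparison, miR159 stood at 8421 against 9325 RPM. Other mature sequences differed between replicates too. In nrpb/d/e11-1 miR160, counted among the other loci, stood at 3.17 RPM in replicate 2 and 12.7 RPM in replicate 1. In iyo-4 miR172 stood at 4.43 RPM in replicate 1 and 19.6 RPM in replicate 2, and miR173 at 47.3 and 154 RPM. Both replicates of a genotype carry the same mutation, so the design gives no biological explanation to test, and what set these libraries apart stays open.

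CHH methylation at pseudogenes was higher in iyo-4 and qqt2-2 than in wild type. Incomplete conversion is argued against, since the higher chloroplast level of these mutants, 0.9393%, was below the 1.04% of wild type. A shift of coverage toward methylated cytosines may account for part of it: with wild-type coverage as weights the smaller difference was 0.2919 points, in iyo-4, which kept 35.43% of its difference over the same cytosines, while qqt2-2 kept 59.94%. What remains, an effect of the mutations included, stays open with 1 library per genotype.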

How the results depend on the processing

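Alternatives with reads outside structural RNA and chloroplast as library size, without reads 1 change from structural RNA, and without the high-coverage stretch of chromosome 2 were chosen after seeing the data. Alternatives by transposon superfamily and length class were not run, because such annotation was not used here. Unless said otherwise, values stand in the order iyo-4, qqt2-2, nrpb/d/e11-1, and the cause of a changed value was not tested. When 1 library was left out, the remaining library of that genotype was assumed to vary like the others.

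Of 123 alternative counts of windows 74 stayed within 1.5 times the count reported and 49 did not, and of 60 counts of loci 26 did and 34 did not. Of 665 alternative values of named windows 642 kept direction and side of the threshold, 22 no longer passed and 1 reversed. Of 1076 values of named loci 921 did, 67 no longer passed, 41 newly passed and 47 reversed. Of 11 values of the 24-nt share 7 did and 4 no longer passed, among them those without a wild-type library, where 7 splits allow no p below 0.143; per distinct sequence it was -20.3 points (p = 0.0714) and per miRNA read -1.68 (p = 0.393), by exact permutation. The value per miRNA read counts all 24-nt reads, rDNA fragments included. Named flanks kept their direction, with 25 of 36 values within their interval.

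With TMM factors on the windows, lower windows numbered 4603, 8891 and 9883 and higher windows 2222, 7403 and 1041. The median log2 changes were -0.50, 0.03 and -5.95, the last mostly from windows with no read, which bounds no fold. Windows that differed numbered 1805 for qqt2-2 against iyo-4, 1749 for nrpb/d/e11-1 against iyo-4 and 8458 for nrpb/d/e11-1 against qqt2-2. The odds ratio with CHH loss was 12.1 in qqt2-2 and 9.66 in nrpb/d/e11-1. By class, fry turned up in iyo-4 for gene bodies (median log2 change -0.74), pseudogenes (0.10) and pericentromeres (-0.0233), and in qqt2-2 for other intergenic sequence (0.0396), pseudogenes (0.63) and pericentromeres (0.54); it no longer passed for other intergenic sequence in iyo-4 (-0.42, adjusted p 0.0655) and gene bodies in nrpb/d/e11-1 (-5.67, adjusted p 0.114).

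With reads outside structural RNA and chloroplast as library size, lower windows numbered 18254, 14040 and 18849 and higher windows 1038, 1803 and 928 of 20161 tested, and windows that differed 12457 for qqt2-2 against iyo-4, 1939 for nrpb/d/e11-1 against iyo-4 and 17115 for nrpb/d/e11-1 against qqt2-2. Lower loci numbered 5, 4 and 8 and higher loci 108, 96 and 94. Log2 changes that reversed in iyo-4 were miR171 1.505, miR159 1.34, miR167 0.97, miR156 1.201, miR163 1.07, miR398 0.91, miR396 1.06, miR393 1.44, miR164 1.39, miR168 1.15 and TAS3a 1.26, and in qqt2-2 miR398 0.69. In nrpb/d/e11-1 they were miR398 0.0416, miR171 1.69, miR159 1.61, miR167 1.16, miR156 0.58, miR163 0.94, miR396 0.24, miR172 1.64, miR390 2.34, miR160 2.12, miR393 2.03, miR319 1.15, miR403 1.74, miR164 1.77, miR173 2.28, miR168 1.26, miR162 0.90, TAS1a 1.51, TAS1b 0.92, TAS1c 0.80, TAS2 1.075, TAS3a 1.17, TAS3b 1.29, TAS3c 1.71 and TAS4 1.68.

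With TMM factors on the loci, lower and higher loci numbered 17 and 4 in qqt2-2 and 34 and 28 in nrpb/d/e11-1, where miR159 (0.11), miR390 (0.84), miR160 (0.60), miR393 (0.52), miR173 (0.78), TAS1a (0.0048) and TAS4 (0.18) reversed. With DESeq2 and its own size factors, higher loci numbered 3 in qqt2-2, lower and higher loci 30 and 15 in nrpb/d/e11-1, and miR390 (0.74), miR173 (0.66) and TAS4 (0.0646) reversed in nrpb/d/e11-1. Higher windows then numbered 565 in iyo-4 and 608 in nrpb/d/e11-1, and windows that differed 8021 for qqt2-2 against iyo-4, 1098 for nrpb/d/e11-1 against iyo-4 and 15062 for nrpb/d/e11-1 against qqt2-2. With DESeq2 and total reads as size, higher windows numbered 76 in iyo-4 and 174 in qqt2-2. With reads at miRNA loci as library size, higher windows numbered 93 in qqt2-2 and 615 in nrpb/d/e11-1, and windows that differed between nrpb/d/e11-1 and iyo-4 818.

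With no filter on low counts, more windows were tested; lower windows numbered 74298 in iyo-4 and 89320 in nrpb/d/e11-1, higher windows 301 and 422, windows that differed between nrpb/d/e11-1 and iyo-4 3049, higher loci in iyo-4 3 and lower loci in qqt2-2 17. With only reads of 1 place, which leaves fewer reads, lower windows numbered 17422, 14088 and 17540, higher windows 1.7e+02 (rounded) in qqt2-2 and 73 in nrpb/d/e11-1, and windows that differed 12227 for qqt2-2 against iyo-4, 2218 for nrpb/d/e11-1 against iyo-4 and 15602 for nrpb/d/e11-1 against qqt2-2; the AT1G66290 window of nrpb/d/e11-1 reversed to -6.68. With reads of all lengths, lower loci numbered 33 in iyo-4 and 30 in qqt2-2. With a replicate block, which pairs libraries that merely share a number (correlations of -0.01712 to 0.01023), higher loci numbered 3 in iyo-4, and lower and higher loci 5 and 7 in qqt2-2.

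With each library left out in turn, higher windows ranged from 73 to 115 in iyo-4, 154 to 292 in qqt2-2 and 78 to 145 in nrpb/d/e11-1, and windows that differed between nrpb/d/e11-1 and iyo-4 from 955 to 2858. Lower loci ranged from 4 to 13, 3 to 9 and 38 to 68, and higher loci from 1 to 4, 1 to 4 and 2 to 5. The difference in 24-nt share ranged from -14.7 to -12.9 points.

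As a mean over cytosines, the differences from wild type were 0.376, 0.106 and 0.294 points in CG, -0.561, -0.275 and -0.515 in CHG, reversed in iyo-4 and qqt2-2, and -0.686, -0.382 and -0.996 in CHH. With at least 10 reads per cytosine they were 2.24, 1.97 and 0.290 in CG, -0.505 (reversed), 0.263 and -1.40 in CHG, -1.20, -0.595 and -1.71 in CHH, and -12.97, -7.94 and -14.7 at 24-nt siRNA windows. Corrected by the chloroplast level they were 3.66, 2.81 and 1.08 in CG, 0.807, 1.09 and -0.673 in CHG and -0.687, -0.238 and -1.35 in CHH. Without the high-coverage stretch of chromosome 2 they were 3.604, 2.77 and 1.11 in CG, 0.687 in iyo-4 and -0.728 in nrpb/d/e11-1 in CHG, and -0.801, -0.342 and -1.43 in CHH.

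By class, with at least 10 reads per cytosine, CG reversed in nrpb/d/e11-1 in pericentromeres (-0.263) and arms (-0.178), and CHG in gene bodies of iyo-4 (-0.0374) and qqt2-2 (-0.0258), pericentromeres of nrpb/d/e11-1 (-0.695) and arms of qqt2-2 (-0.703). CHH differences were -0.296, -0.197 and -0.472 in gene bodies, 0.698, 1.17 and -1.77 in pseudogenes, -2.25, -1.49 and -2.52 within 1 kb of genes, -2.30, -1.28 and -3.20 in other intergenic sequence, -1.23, -0.441 and -2.58 in pericentromeres and -1.34, -0.824 and -1.65 in arms.

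Larger thresholds of 0.6, 0.3 and 0.15 call fewer windows by construction: hypo- and hypermethylated windows numbered 92 and 41 in CG, 6213 and 215 in CHG and 16905 and 127 in CHH in iyo-4, 16 and 3, 1808 and 64, and 8989 and 138 in qqt2-2, and 433 and 66, 7735 and 239, and 19128 and 36 in nrpb/d/e11-1. Windows of 200 bp are fewer; they gave 318 hypermethylated CG windows and 14328 and 154 in CHH in iyo-4, 156 and 45 in CG and 8543 and 181 in CHH in qqt2-2, and 327 hypermethylated in CG, 580 in CHG and 16341 and 19 in CHH in nrpb/d/e11-1. With at least 10 reads per cytosine fewer windows were tested; hypomethylated CG windows numbered 325 in iyo-4 and 160 in qqt2-2, hypermethylated CG windows 367, 60 and 496, and hypermethylated CHH windows 47 in nrpb/d/e11-1.

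At 24-nt siRNA windows of at least 20 RPM the CHH differences were -11.2, -6.15 and -13.5 points, and with the threshold met in the wild-type mean -10.7, -6.47 and -12.2. The odds ratio within quartiles of the wild-type level was 1.93 in iyo-4 and 3.95 in nrpb/d/e11-1, and with a CHH threshold of 0.05 17.3 in qqt2-2 and 10.06 in nrpb/d/e11-1. Depth limits the windows with no mutant read, which allow up to 3 counts per library, and tests on simulated data recovered 36.1%, 51.7% and 40.6% of windows lowered 2-fold.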

Other observations

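The tests of this part were set before their results were seen.

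Windows that lost 24-nt siRNAs in iyo-4 and in qqt2-2 differed in what was left. Of the lower windows, 4743 in iyo-4 and 23564 in qqt2-2 still held at least 10 reads of 18 to 30 nt, with a median 24-nt share of 67.6% in both (lower quartiles 40.5% and 59.5%), beside 67.7% and 68.4% at all lower windows in wild type. Windows that held fewer are left out of these medians. Over the summed reads of all lower windows the 24-nt share was 36.3% in iyo-4 against 63.7% in wild type, and 58.3% in qqt2-2 against 67.2%. In nrpb/d/e11-1 1209 lower windows held as many, and their median 24-nt share was 11.5%.

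Because qqt2-2 kept part of both its 24-nt siRNAs and its CHH methylation, a hypothesis was that windows that kept more of the first kept more of the second. Spearman's rho between the 24-nt change and the share of CHH methylation kept was 0.662 across windows, and 0.6086 in the chromosome with the lowest value, above the value set for the hypothesis; windows are not independent replicates and no p is given. It was also 0.5095 in iyo-4 and 0.5094 in nrpb/d/e11-1, where 86.9% of the lower windows had no read, so a relation of this kind arose with hardly any 24-nt reads kept and the value does not tie kept methylation to kept siRNAs. In qqt2-2 it was 0.761 in the arms and 0.363 in the pericentromeres, and 0.116 in pseudogenes, where the median window kept 108.8% of its CHH methylation against 46.1% within 1 kb of genes. The relation may therefore be weak where pseudogenes, a class that here includes transposable elements, hold CHH methylation by other means, which was not tested.

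A further hypothesis was that pseudogene windows that gained CHH methylation lost fewer 24-nt reads. The tables argue against it: over the 285 such windows of iyo-4 the median log2 change was -3.80 against -3.91 over all 8605, over the 315 of qqt2-2 -1.14 against -1.17 over 8616, and the smaller difference of medians was 0.0294.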
